A study of Populus tremula x Populus alba with 6 samples.

How the data were processed

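Mobilome-seq libraries were analysed from shoot apical meristems of a clone of the hybrid poplar Populus tremula x Populus alba. There were 6 libraries, 1 for each of 6 groups: wild type (WT), ddm1 RNAi line 15 and ddm1 RNAi line 23, each under control watering and after drought followed by rewatering. Per the labels' protocols, DNA was extracted with CTAB, extrachromosomal DNA was amplified, libraries were made with Nextera XT, and fragments were read from both ends (2 reads of 250 bp) on an Illumina MiSeq. Bowtie2 is named in the submitters' processing notes, with no version. The genome build, the counting tool and the filters are not given in the sources used here.

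The deposited tables hold 1 list of transposable element (TE) loci per library, and each list was assigned to the sample whose title is the name of its sheet. Each locus has a chromosome, a start, an end, a length and 1 to 3 TE family names. Per the file headers, each locus carries a coverage signal headed DOC and another headed SR, read here as depth of coverage and split reads, since the headers do not spell the abbreviations out. Split reads would be reads that cross a junction, such as the closure of a circle. Both are deposited as whole numbers with no scaling to library size, and whether they are read counts or a depth is not stated, so they were treated as signal and no count model was fitted. Of the depth values up to 20, 78.4% were even, against 65.3% of those above 20. In 66 of 665 entries the split-read value exceeded the depth value. Per the file headers, the tables also give the part of each locus covered by each signal, headed as a percent but deposited as a fraction from 0 to 1.

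The lowest listed depth value was 3, the lowest split-read value was 3, the lowest fraction covered by depth was 0.801 and the shortest locus was 99 bp. These are observed minima, and the authors' threshold for listing a locus is not given in the sources used here. A locus missing from a list was therefore called unlisted, never absent. Listed length equalled end minus start in all 665 entries, so starts were taken as counted from 0 and are given here counted from 1. No reference sequence or gene annotation was used, so neither the sequence of a locus nor its position relative to genes is given. Total reads per library are not used here, and the summed signal of a list of selected loci is not a sequencing depth.

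Loci were matched between libraries by overlap of at least 1 bp, and overlapping loci always had identical coordinates. Each locus was given a class from its first family name: Gypsy (Ogre families included), Copia, non-LTR (LINE and SINE), DNA transposon (CACTA/EnSpm, hAT, PIF/Harbinger and DNA-3), Helitron, or other (satellites and simple repeats). Several names were given in 411 entries, and they belonged to more than 1 class in 39. Loci are called by their first name below. Of those discussed, SAT-1_PT on chromosome 11 and L1-1_PTr on chromosome 8 also carried a Gypsy name. Gypsy-72_PTr-LTR at 38198036 on chromosome 1 also carried a Helitron name. No locus was named as chloroplast, mitochondrial or ribosomal DNA. Before the data were examined, the loci to be named were fixed as the 5 with the highest depth value per library, every locus listed in both drought-rewatered RNAi libraries and in neither WT library, and every locus listed in all 6 libraries. The rule gave 24 loci. Loci listed in all control libraries only, or in all drought-rewatered libraries only, were named after their values were seen.

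With 1 library per group, no spread within a group exists. The effect of drought and rewatering was tested with a two-sided exact sign-flip test over 3 genotypes, whose smallest possible p is 0.25. The RNAi and WT libraries were compared with a two-sided exact permutation test over 15 splits, whose smallest possible p is 0.0667. Neither test could pass a threshold of 0.05. A permutation with libraries matched by watering, over 9 splits, was added after the data were seen. Class shares of single lists were compared with Fisher's exact test, two-sided, which compares lists and not conditions, with Benjamini-Hochberg adjustment over 35 tests. Zelen's exact test of equal odds ratios asked whether the drought and control lists differed in a class share alike in all genotypes. Like Fisher's test, it compares lists and not conditions. Zelen's test replaced a binomial model with a parametric bootstrap of 2000 draws after the values were seen. No class passed an adjusted p of 0.05 under either. Number intervals are 95% Poisson intervals and share intervals are exact 95% Clopper-Pearson intervals. Intervals of the ratio of numbers, drought over control, were derived from the exact 95% binomial interval of the drought part. They treat both lists of a genotype as independent counts, although some loci are in both, and compare lists and not conditions. All these intervals cover counting error only, since amplified circles are not independent molecules.

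Sets of shared loci were set beside 10000 random lists in which the number of loci per library and the number of libraries per locus were held fixed. This comparison was chosen after the lists were seen. It was tested on simulated lists of 436 loci: with nothing planted, 2% of 50 simulations had p under 0.05, and with 10 planted control-only loci 70% did. The tests of LTR against internal parts, the ratios at loci listed in both libraries of a genotype, and the DNA-3 share of depth were also chosen after the data were seen. Alternatives covered stricter minima for listing, merging of loci within 1000 or 10000 bp, other definitions of a shared locus, other weights and class rules for shares, other scalings of depth, and leaving out each genotype. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.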

Results

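Active transposable elements can leave extrachromosomal circular DNA, which mobilome-seq enriches by amplification before sequencing. The assay was applied to shoot apical meristems of WT poplar and of 2 RNAi lines, 15 and 23, directed against ddm1. DDM1 is a chromatin remodeller known to maintain DNA methylation and TE silencing. The level of the RNAi target itself is not measured by this DNA assay. Plants were kept under control watering or exposed to drought and rewatered, with 1 library per genotype and watering, so no value below has a replicate. Across the 6 libraries, 436 loci on 19 chromosomes were listed, making 665 entries. The summed depth value of the listed loci was 92011 in WT control, 30529 in WT drought, 69585 in line 15 control, 50114 in line 15 drought, 44510 in line 23 control and 22388 in line 23 drought. Coordinates are those of the deposited tables.

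The first comparison asked how the set of listed TE loci differed after drought and rewatering. Fewer loci were listed after drought in each of the 3 genotypes. WT had 149 loci under control watering (95% Poisson interval 126 to 175) and 115 after drought (94.9 to 138), a ratio of 0.772 (0.600 to 0.991), whose interval reached past 1 when loci within 1000 bp were merged (0.790, 0.612 to 1.02). Line 15 had 169 (144 to 196) and 79 (62.5 to 98.5), a ratio of 0.467 (0.353 to 0.614), and line 23 had 109 (89.5 to 131) and 44 (32.0 to 59.1), a ratio of 0.404 (0.278 to 0.578). The mean difference was -63 loci (SD 28.1, n = 3 genotypes, exact two-sided sign-flip p = 0.25, adjusted p = 0.9). An unadjusted p of 0.25 is the smallest that 3 genotypes allow. The ratios of the genotypes were not tested against each other, and with depth at least 20 in every library they were 0.606 in WT (0.432 to 0.844), 0.482 in line 15 (0.340 to 0.675) and 0.348 in line 23 (0.209 to 0.561). At loci listed in both libraries of a genotype, the median log2 ratio of depth values, drought over control, was -0.38 in WT (38 loci, 95% bootstrap interval -0.47 to -0.05), -0.32 in line 15 (30 loci, -0.82 to 0.07) and -0.55 in line 23 (15 loci, -1.19 to -0.0056), a measure chosen after the data were seen.

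**Figure D1:**
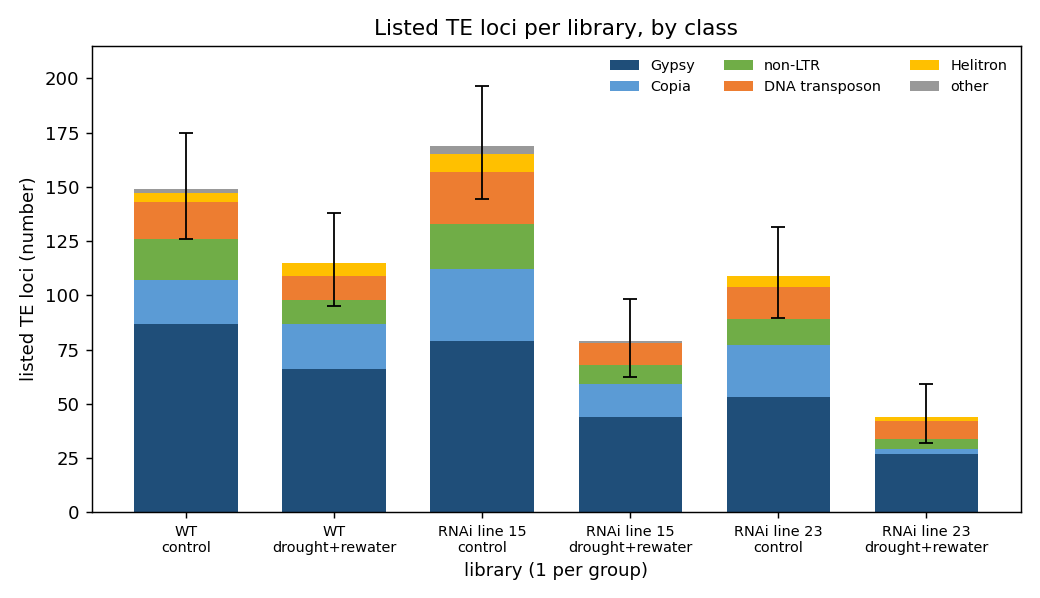
Number of listed TE loci (vertical axis) in each of the 6 libraries (horizontal axis), stacked by TE class, with error bars giving the 95% Poisson interval of the total. The drought-rewatered library of each genotype lies below its control library, from 149 to 115 in WT, from 169 to 79 in line 15 and from 109 to 44 in line 23.

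Gypsy elements, long terminal repeat (LTR) retrotransposons, made up the largest class in all 6 lists. They accounted for 87 of 149 loci in WT control (58.4%, exact 95% interval 50.04 to 66.4) and 66 of 115 in WT drought (57.4%, 47.8 to 66.6). In the RNAi lines the Gypsy share was 46.7% under control watering and 55.7% after drought in line 15, and 48.6% and 61.4% in line 23. Ogre elements, a lineage of very large Gypsy retrotransposons, supplied between 6 and 19 loci per library. Copia, the other main LTR superfamily, held 20 loci in WT control and 21 in WT drought, 33 and 15 in line 15, and 24 and 2 in line 23. Helitrons, which transpose by a rolling-circle mechanism, numbered 4 and 6 in WT, 8 and 0 in line 15, and 5 and 2 in line 23.

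None of 35 Fisher's exact tests of class shares between lists passed an adjusted p of 0.05, and 3 had an unadjusted p under 0.05. The lowest was for Copia in line 23, 4.55% after drought against 22.0% in control (Fisher's exact p = 0.00838, adjusted p = 0.293). Zelen's exact test of a drought effect on the Copia share that differs between genotypes gave p = 0.0149, which did not pass after adjustment over the 5 classes (adjusted p = 0.0745). Over the 3 genotypes the mean change was 6.90 percentage points for Gypsy (SD 7.10, exact sign-flip p = 0.5) and -4.39 for Copia (SD 11.6, exact sign-flip p = 0.75). Weighted by length, the Gypsy value was 17.0 and the Copia value -13.3, each in the same direction in 3 of 3 genotypes (exact sign-flip p = 0.25, the smallest possible). The Gypsy value turned to -10.9 when loci were weighted by depth, and the Copia value was -0.851 weighted by depth and turned to 2.15 without line 23. The length-weighted values include 1 Gypsy locus of 8194 bp on chromosome 13, listed after drought in each genotype but under control watering in WT alone. Total listed length after drought was 54494 bp in WT, 44144 bp in line 15 and 27097 bp in line 23. The values without that locus were not computed.

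The locus with the highest depth value differed between the waterings. Under control watering it was a 221 bp internal fragment of Gypsy23-PTR_I-int on chromosome 1 (44984628 to 44984848), with depth values of 49200 in WT, 51684 in line 15 and 36388 in line 23 and split-read values of 943, 1105 and 722. This locus was unlisted in all 3 drought-rewatered libraries. There the first place was taken in each genotype by Gypsy-27_PTr-I-int on chromosome 13 (8689906 to 8698099, 8194 bp), with depth values of 22796 in WT, 24823 in line 15 and 14317 in line 23. Gypsy-27_PTr-I-int was also listed in WT control (20299, rank 2) but not in the control libraries of the RNAi lines, and its split-read values lay between 6 and 13. The leading locus held between 49.5% and 81.8% of the summed depth of its list. Ranks and shares use the values as deposited, not divided by locus length, which was 221 bp and 8194 bp for these leading loci. If the values are read counts, longer loci would be favoured. A locus named first as a satellite, SAT-1_PT on chromosome 11 (9097155 to 9103437), also carried the name Gypsy-78_PTr-I-int. Its depth values were 6927 in WT control, 5202 in line 15 control and 9069 in line 15 drought, with split-read values of 10 or less.

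Beside the Gypsy23 locus, 4 others were listed in all 3 control libraries and in no drought-rewatered one, making 5 in all. They were singled out after their values were seen. They carried Gypsy13-PTR_I-int (chromosome 4, 5437039 to 5437693), Copia43-PTR_I-int (chromosome 6, 19735960 to 19737070), DNA-3-3_PTr (chromosome 6, 9140343 to 9140489) and L1-2_PTr (chromosome 8, 89800 to 90056). The highest of their depth values was 384, at Gypsy13-PTR_I-int in WT control. Random lists with the same totals held a mean of 4.90 such loci, and a share of 0.559 of them held at least 5. The reverse, listing in all 3 drought-rewatered libraries and in no control, was found for 1 locus, Copia9-PTR_LTR on chromosome 18 (7702141 to 7702329), with depth values of 35 in WT, 53 in line 15 and 84 in line 23 (random mean 0.362).

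Listing in all 6 libraries was found for 7 loci, at which depth could be compared in every genotype. The depth value was lower after drought in 3 of 3 genotypes at 3 of them. ENSPM1_PT, a CACTA transposon on chromosome 14 (4297763 to 4298011), had a mean log2 ratio of -2.75 (SD 2.80, n = 3, exact sign-flip p = 0.25). Ogre-PT2_I-int on chromosome 1 (17789768 to 17790313) had -1.29 (SD 0.34, n = 3, exact sign-flip p = 0.25), and Gypsy-72_PTr-LTR on chromosome 1 (38198036 to 38198481) had -0.71 (SD 0.22, n = 3, exact sign-flip p = 0.25). The mean for Gypsy-72_PTr-LTR turned to 0.31 when depth was divided by the library's sum and to 0.60 on ranks. The mean for Ogre-PT2_I-int shrank to -0.27 on division by the sum (lower in 2 of 3 genotypes) and to -0.27 on ranks (3 of 3), and that for ENSPM1_PT to -1.73 and -1.38 (2 of 3 on both scales). The other 4 loci, Ogre-PT2_I-int (chromosome 1, 41624029 to 41624889), GYPOT1_I-int (chromosome 1, 36180667 to 36181680), L1-1_PTr (chromosome 8, 15378192 to 15378803) and SINE2-2_PTr (chromosome 6, 2112611 to 2112800), went in different directions between genotypes on the values as deposited, and GYPOT1_I-int no longer did on division by the sum or on ranks.

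**Figure D2:**
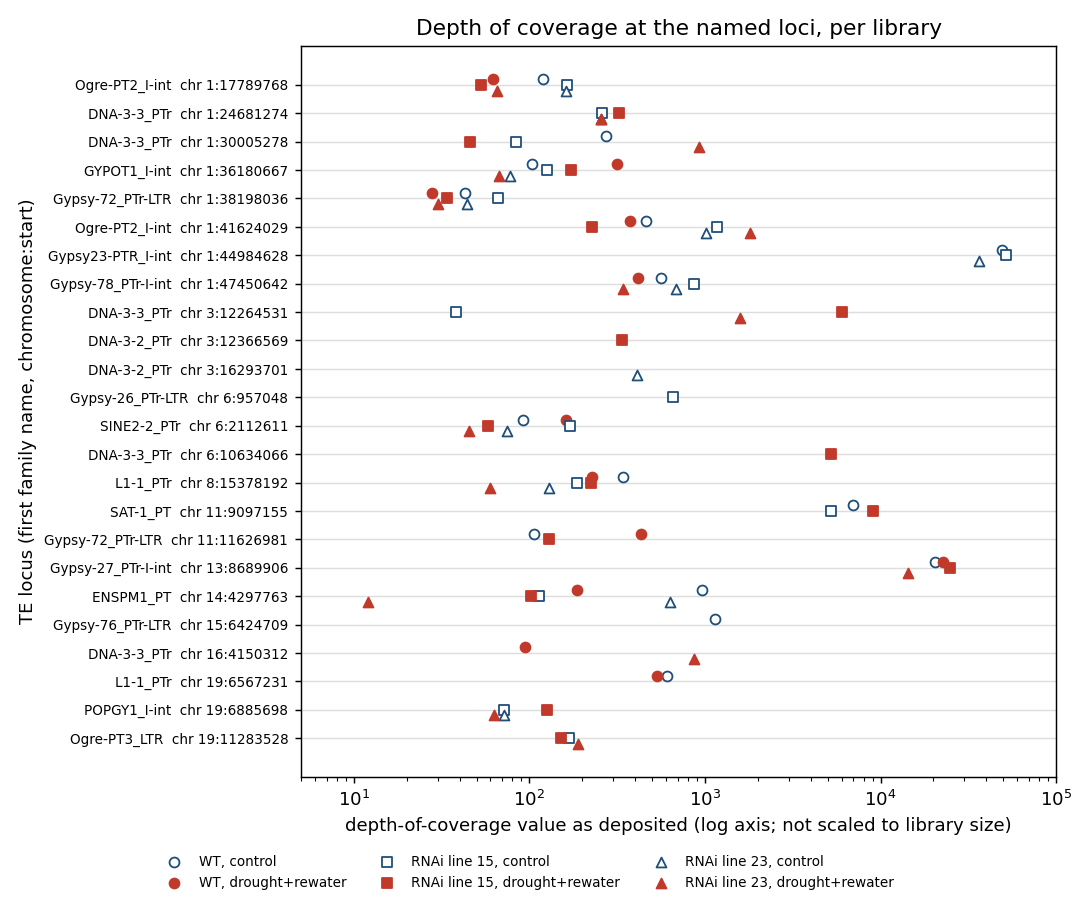
Depth-of-coverage value as deposited (horizontal log axis, not scaled to library size) at the 24 loci named by the rule (vertical axis, first family name with chromosome and start), with 1 point per library in which the locus was listed, open for control and filled for drought. Gypsy23-PTR_I-int on chromosome 1 has 3 open points between 36388 and 51684 and no filled point, and DNA-3-3_PTr at 12264531 on chromosome 3 has filled points only for the RNAi lines, at 6033 and 1577, and an open one at 38.

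The second comparison set the RNAi lines against WT. The 4 RNAi libraries had a mean of 100.25 loci (SD 53.0, n = 4) and the 2 WT libraries a mean of 132 (115 and 149), a difference of -31.75 (exact two-sided permutation p = 0.467). The SD spans both waterings. Under control watering the RNAi lines lay on either side of WT (169 and 109 against 149, a mean difference of -10), and after drought both lay below it (79 and 44 against 115, a mean difference of -53.5). With libraries matched by watering, the exact two-sided permutation p over 9 splits was 0.333, where 0.111 is the smallest possible, and whether the difference depended on watering was not tested. DNA transposons made up 14.7% of loci in the RNAi libraries (SD 2.41, n = 4) and 10.5% in the WT libraries (9.57% and 11.4%), with an exact permutation p of 0.133 and an adjusted p of 0.8 (0.222 and 0.667 with libraries matched by watering). Gypsy made up 53.1% (SD 6.72, n = 4) against 57.9% in WT (exact permutation p = 0.4), and Copia 16.3% (SD 7.93, n = 4) against 15.8% (exact permutation p = 0.933). Split by watering, RNAi minus WT was 7.35 percentage points for Copia under control watering and -6.49 after drought. It was -10.7 and 1.14 for Gypsy, and 2.57 and 5.85 for DNA transposons. After drought the lines lay on either side of WT for Copia and Gypsy. Copia was then 19.0% in line 15 and 4.55% in line 23 against 18.3% in WT, and Gypsy 55.7% and 61.4% against 57.4%. With libraries matched by watering the exact two-sided permutation p was 0.889 for Copia and 0.333 for Gypsy, and whether the RNAi minus WT share depended on watering was not tested. Among 7 loci listed in all 6 libraries, the lowest exact permutation p for RNAi against WT was 0.133, at L1-1_PTr on chromosome 8, with a log2 difference of -1.05. That difference was -0.75 on division by the library's sum and -0.12 on ranks (exact permutation p = 0.933).

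Listing in all 4 RNAi libraries and in neither WT library was found for 2 loci. DNA-3-3_PTr on chromosome 1 (24681274 to 24681590) had depth values of 258 and 324 in line 15 and 257 and 256 in line 23, for control and drought in that order. POPGY1_I-int, a Gypsy element on chromosome 19 (6885698 to 6886242), had 72 and 126 in line 15 and 72 and 63 in line 23. Random lists held a mean of 0.424 such loci, and a share of 0.0640 held at least 2 (one-sided randomisation). In the other direction, 8 loci were listed in both WT libraries and in no RNAi library, against a random mean of 5.20. A share of 0.139 of random lists held at least 8 (one-sided randomisation). Several sets were compared with random lists, and the shares were not adjusted for their number.

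The third comparison asked which loci appeared in the RNAi lines after drought. In both drought-rewatered RNAi libraries and in neither WT library, 4 loci were listed: the DNA-3-3_PTr and POPGY1_I-int loci above, Ogre-PT3_LTR on chromosome 19 (11283528 to 11284050), and a second DNA-3-3_PTr locus on chromosome 3 (12264531 to 12264753). All 4 were also listed in line 15 control, so 0 were listed in the drought-rewatered RNAi pair alone. Ogre-PT3_LTR had depth values of 167 in line 15 control, 152 in line 15 drought and 190 in line 23 drought. The chromosome 3 locus had a depth value of 38 in line 15 control, 6033 in line 15 drought and 1577 in line 23 drought. Its split-read values were 17, 5 and 4681, so its split-read signal was high in line 23 drought alone. Random lists held a mean of 1.97 loci in this set, and a share of 0.125 held at least 4 (one-sided randomisation), while the matching set for the control libraries, both RNAi lines and neither WT, held 10 loci against a random mean of 9.17.

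DNA-3 elements, listed at 5 loci in each drought-rewatered RNAi library, filled 3 of the top 5 places in both. They filled 1 in line 23 control and 0 in the other 3 libraries. Their part of the summed depth was 23.8% in line 15 drought and 16.2% in line 23 drought, against 1.70% in WT control, 1.06% in WT drought, 1.20% in line 15 control and 2.44% in line 23 control. These shares were computed after the data were seen, take no account of locus length and were not tested. Without the chromosome 3 locus they were 13.4% in line 15 drought and 9.90% in line 23 drought. Without a further DNA-3-3_PTr locus on chromosome 6 (10634066 to 10634172, depth value 5202, split-read value 3), listed only in line 15 drought, the line 15 share was 1.82%. The line 23 share likewise fell to 1.45% without the chromosome 3 locus and 2 others, on chromosome 1 (30005278 to 30005537, depth value 918) and chromosome 16 (4150312 to 4150641, 866). The chromosome 1 locus was also listed in WT control (274) and in line 15 (84 in control and 46 after drought), and the chromosome 16 locus in WT drought (94). The number of DNA-3 loci was 6 and 5 in WT, 11 and 5 in line 15, and 6 and 5 in line 23.

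Most loci were listed in a single library. Of the 436 loci, 320 (73.4%) were in 1 library, 51 in 2, 36 in 3, 17 in 4, 5 in 5 and 7 in 6. The 2 libraries of a genotype shared 38 loci in WT, 30 in line 15 and 15 in line 23. Control libraries of different genotypes shared 47, 32 and 39 loci, and drought-rewatered libraries shared 26, 16 and 17. These counts depend on list length. As a percent of the shorter list, the overlaps within WT, line 15 and line 23 were 33.0%, 38.0% and 34.1%. In the order given, they were 31.5%, 29.4% and 35.8% between control libraries and 32.9%, 36.4% and 38.6% between drought-rewatered ones. Across shared loci, which are not independent replicates, Spearman's rho of the depth values lay between 0.460 and 0.908 over the 15 library pairs, with a median of 0.743. Counted by first family name, 13 of 101 names were listed in all 6 libraries.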

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

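Of 10 named loci listed in both libraries of at least 2 genotypes, 6 had depth values that went up after drought in 1 genotype and down in another. None of these differences was tested, and with 1 pair of libraries per genotype mixed directions also arise from noise. The values are log2 ratios of drought over control on the depth values as deposited. The count depends on that choice, since each of the other 4 loci also had opposite directions under at least 1 of the 3 other scalings: Gypsy-78_PTr-I-int on chromosome 1 and ENSPM1_PT under 2, and Ogre-PT2_I-int at 17789768 and Gypsy-72_PTr-LTR under 1.

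At Ogre-PT2_I-int on chromosome 1 (start 41624029) the ratio was -0.30 in WT, -2.36 in line 15 and 0.83 in line 23. At SINE2-2_PTr on chromosome 6 (start 2112611) it was 0.82 in WT, -1.56 in line 15 and -0.74 in line 23. At L1-1_PTr on chromosome 8 (start 15378192) it was -0.60 in WT, 0.27 in line 15 and -1.12 in line 23. These 3 loci had opposite directions under all 3 other scalings as well, though not always in the same genotypes. At GYPOT1_I-int on chromosome 1 (start 36180667) the ratio was 1.59 in WT, 0.45 in line 15 and -0.22 in line 23, and the directions were no longer opposite when depth was divided by the library's sum or ranked. At DNA-3-3_PTr on chromosome 1 (start 24681274), listed in the RNAi lines only, it was 0.33 in line 15 and -0.0056 in line 23, where the depth value went from 257 to 256. At POPGY1_I-int on chromosome 19 (start 6885698), also listed in the RNAi lines only, it was 0.81 in line 15 and -0.19 in line 23. For these last 2 loci the directions were opposite under 1 of the 3 other scalings.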

How the results depend on the processing

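Of 319 values under alternative settings, 241 kept their direction or stayed close to the reported value. The alternatives with a split-read minimum of 10, with depth minima of 15 and 20 in every library, with RNAi and WT matched by watering, without line 23 control as a condition, and without 1 to 3 DNA-3 loci were chosen after seeing the data. Except where a filter removes loci by construction, the cause of a change was not tested. Leaving out organellar or ribosomal loci and leaving out unannotated loci changed nothing to compare, because no such locus was listed, and random placement on the genome was not run because sequence lengths were not used here. Matching RNAi and WT libraries by watering left the differences as they were, since each watering has every genotype, and its exact permutation p lay between 0.222 and 0.889 over the number of loci and 5 class shares.

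Fewer loci after drought held in direction under every listing minimum, merging distance and left-out genotype tried. The WT interval reached past 1 under merging, with a ratio of 0.790 (0.612 to 1.02) at 1000 bp and 0.806 (0.623 to 1.04) at 10000 bp. The mean difference of -63 loci was -25.3 with a split-read value of at least 10. The RNAi minus WT difference of -31.75 was -18 with depth at least 5 times the lowest value, -8 with line 15 alone and -55.5 with line 23 alone. It was -21.75 with depth at least 15 and -15.5 with depth at least 20 in every library. With a split-read value of at least 10 it was -28 (exact permutation p = 0.2). With depth at least 5 times the library's own lowest value, WT kept 110 and 60 loci for control and drought (ratio 0.545), line 15 kept 110 and 59 (0.536), and line 23 kept 72 and 27 (0.375). That minimum is not the same in every library, because the lowest value was 4 in WT drought and line 15 control and 3 in the others. With depth at least 15 in every library, WT kept 110 and 74 (0.673), line 15 kept 123 and 59 (0.480), and line 23 kept 72 and 27 (0.375). With depth at least 20, WT kept 99 and 60 (0.606), line 15 kept 110 and 53 (0.482), and line 23 kept 69 and 24 (0.348). With a split-read value of at least 10, WT kept 73 and 49, line 15 kept 57 and 27, and line 23 kept 35 and 13, for control and drought in that order.

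Weighting by depth moved the Gypsy share to 85.4% in WT control, 91.9% in WT drought, 85.8% in line 15 control, 91.8% in line 23 control and 82.6% in line 23 drought. It moved Copia to 0.985% and 1.71% in WT, 2.29% and 0.808% in line 15, and 2.19% and 0.393% in line 23. It moved DNA transposons to 3.47% and 1.94% in WT, 2.72% and 24.2% in line 15, and 4.16% in line 23 control. Weighting by length moved Gypsy to 73.7% in WT drought, 67.5% in line 15 drought, 61.7% in line 23 control and 85.3% in line 23 drought, and Copia to 7.61% in line 15 drought. It moved DNA transposons to 3.10% and 3.97% in WT, 6.80% and 5.14% in line 15, and 6.78% and 6.42% in line 23.

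Mean changes after drought, in percentage points, reversed for Gypsy weighted by depth (-10.9), Copia without line 23 (2.15), non-LTR weighted by depth (0.221), DNA transposons weighted by length (-0.382) or without line 23 (-1.69), and Helitron counting every class named (0.220) or without line 15 (1.25). Without reversing, the Gypsy change moved to 17.0 weighted by length, 10.8 without WT and 3.98 without line 23, and the Copia change to -13.3 weighted by length, -0.851 weighted by depth and -9.01 without WT. The DNA transposon change moved from 0.344 to 10.7 weighted by depth. RNAi minus WT moved for Gypsy from -4.78 to -1.88 weighted by length and -9.72 weighted by depth. For DNA transposons it moved from 4.21 to 2.75 weighted by length and 9.15 weighted by depth. Its exact permutation p was 0.0667, the smallest possible, when weighted by length and when loci within 1000 bp were merged (4.34). RNAi minus WT reversed for Copia weighted by length (-1.91) or with line 23 alone (-2.56), for non-LTR weighted by length (-1.59) or depth (-1.98, also at the smallest exact permutation p of 0.0667), and for Helitron counting every class named (0.472), weighted by length (0.427) or with line 23 alone (0.615).

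Counting a shared first family name as sharing gave 27 for the line 23 pair, 13 names in all 6 libraries and 29 in 1 library. The 4 loci of both drought-rewatered RNAi libraries became 0 when also required to be unlisted in both control RNAi libraries, and 2 when unlisted in line 23 control only. Mean log2 depth ratios after drought reversed on division by the library's sum for Ogre-PT2_I-int at 41624029 (0.41), L1-1_PTr (0.54), SINE2-2_PTr (0.53) and Gypsy-72_PTr-LTR (0.31), and on ranks for L1-1_PTr (0.56), SINE2-2_PTr (0.47) and Gypsy-72_PTr-LTR (0.60). The RNAi minus WT value of SINE2-2_PTr reversed on ranks (0.17). Division by the sum depends on 1 locus, since the leading locus held at least 49.5% of each sum.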

Other observations

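By first family name, Gypsy-72_PTr-LTR was listed most often, with 9 and 11 loci in WT, 7 and 10 in line 15, and 4 and 1 in line 23, for control and drought in that order. SINE2-2_PTr, a short interspersed element, had 6 and 3 loci in WT, 12 and 3 in line 15, and 3 and 3 in line 23. Gypsy-71_PTr-LTR had 4 and 4 in WT, 9 and 0 in line 15, and 4 and 3 in line 23. Elements of the hAT superfamily were listed only in control libraries, 2 in WT and 5 in line 15. None of these counts was tested. The Gypsy23-PTR_I-int fragment that led the control lists had neighbours of the same name on chromosome 1. The one at 44974374 to 44975801 had depth values of 71 in WT control, 79 in line 15 control and 27 in line 23 drought. The one at 44982256 to 44983760 had 74 in WT control and 106 in line 15 control.

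Among Copia loci in WT, 6 of 20 were named as LTR under control watering and 17 of 21 after drought (Fisher's exact p = 0.00158, adjusted p = 0.00948 over 6 tests). The other 5 tests, for Gypsy in WT and for Gypsy and Copia in the RNAi lines, did not pass, and the difference between genotypes was not tested. The test compares 2 lists and was chosen after the data were seen.

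All tests in the following paragraphs were chosen after the lists were seen. The values behind the depth ratio, the top-locus share and the expected split-read value at Gypsy23-PTR_I-int had been seen when those tests were framed, and the test on loci far above the listing minimum was added after the depth ratio left the question open.

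Fewer loci were listed after drought in all 3 genotypes. The leading locus took a larger share of the summed listed depth after drought in 1 of 3 genotypes, WT. This cannot decide whether a dominant locus crowded out others, because the sum covers listed loci only and is not a sequencing depth. Lower coverage may contribute and stays open: the median log2 depth ratio was -0.32 at its highest, in line 15 (95% bootstrap interval -0.82 to 0.07), and its intervals lay below 0 in WT (-0.47 to -0.05) and line 23 (-1.19 to -0.0056), over loci that had to be listed in both libraries. Of control loci far above the minimum (depth at least 50, split reads at least 12, at least 95% covered), 17 of 40 were unlisted after drought, against 9 of 20 in reverse (Fisher's exact p = 1, two-sided), too few to decide. An effect of drought on circle formation is untested here and cannot be told apart from library yield with 1 library per group.

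The Gypsy23-PTR_I-int locus led all 3 control lists and was unlisted in all 3 drought-rewatered ones. The number of loci with that listing, 5, was reached in a share of 0.559 of random lists, which take no account of depth. A uniform loss of coverage taking this locus under the lowest listed split-read value of 3 would also have taken loci with lower values. In WT control and line 15 control its split-read value was the highest listed, yet 38 and 30 loci stayed listed after drought. This argues against a uniform loss of that size in those genotypes. At the lower bound of the median split-read ratio over loci listed in both libraries, the locus would have kept 321 in line 23, the lowest of the genotypes. At the lowest ratio of any single such locus it would have kept 39.4. These expected values do not test the cause, since only loci that kept at least 3 after drought have a ratio. Loci that dropped out are not in these ratios and the authors' threshold is not known, so a larger loss at this locus is not ruled out. The direction was the same in 3 of 3 genotypes, for which no exact two-sided sign-flip p below 0.25 is possible. An effect of drought on this locus is a hypothesis that these 6 libraries do not decide.

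Most loci were listed in 1 library. Their depth values were lower than those of the other loci in 6 of 6 libraries (permutation test, highest adjusted p = 0.00116), for example a median of 20 against 71.5 in WT control. Lower coverage may therefore contribute to the single listing, but how much was not measured. The medians of single-library loci, from 10 in line 23 drought to 20 in WT control and line 15 control, lay above the lowest listed value of 3. With depth at least 2 times the lowest listed value, 274 loci were in 1 library, against 320 without that minimum. That count can include shared loci whose other entries were removed, so it does not show how much low coverage contributes. Far above the minimum, 17 of 40 control loci were unlisted after drought and 9 of 20 drought loci in control. Circles present in 1 sample only were not tested as an alternative.

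The hypothesis that loci shared by both drought-rewatered RNAi libraries and unlisted in WT exceed chance was neither shown nor excluded. A share of 0.125 of random lists held at least 4 such loci, against a random mean of 1.97. The comparison with random lists was tried on simulated lists with planted control-only loci. It was not tried with loci planted in this set, so its power here is not known.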
